A study of Mus musculus with 6 samples.

How the data were processed

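RNA from cultured mouse aortic smooth muscle cells was sequenced in 6 libraries, 3 from cells given trimethylamine N-oxide (TMAO) for 48 h and 3 from control cells. Each library was assigned to its group and replicate number by its title. The dose of TMAO and the sex and number of mice are not given in the sources used here. The labels give 3 samples per group without saying whether they came from separate animals, so p-values measure the spread between these samples, which may be technical.

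The authors deposited one table per library with a gene identifier, a symbol and a value in FPKM, fragments per kilobase of exon scaled to the library total. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a stranded poly(A) RNA kit. Trimmomatic, HISAT2, Cufflinks and HTSeq and the genome build mm10 are named in the submitters' processing notes, with no versions. The annotation release and the strand setting of the counting are not given in the sources used here. The header of the Control 1 column spells the unit PKM, and its values follow the same steps of length and depth as the columns headed FPKM. The tables list 25939 genes, none of them at 0 in all 6 libraries.

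An FPKM value fixes the number of reads once the exon length and the library total are known. Exon lengths from GENCODE release M21, on the same mm10 build, held 25885 of the listed identifiers, and 54 identifiers were not in it. With 1 total per library, the deposited FPKM values of 25499 genes gave whole numbers of reads in all 6 libraries, to within 0.01 reads. These are 98.5% of the annotated genes. The totals implied in this way were 15015258, 15064527 and 16806728 reads for Control 1 to 3 and 16524834, 15951831 and 14991252 reads for TMAO 1 to 3. A single read in 1 kb of exon was then worth 0.0595 to 0.0667 FPKM. Coordinates and exon overlaps come from the same annotation.

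FPKM values are not counts, so the comparison used limma 3.58.1 in R 4.3.3, with a trended and robust variance, on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, 11062 in all. Fold changes on this scale understate the change of low genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A test for count tables had been foreseen as the main one in case the tables held counts, and the test for normalized values, foreseen beside it, was used. Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, two-sided, and adjusted over the 29 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Members were also counted as past the threshold when adjusted over the list alone.

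The groups, the test, the alternatives, the 35 gene lists and the rule for named genes were chosen before the data were examined. The rule took genes past the threshold with a mean of at least 1 FPKM, a symbol that is not a predicted gene model, and all 3 TMAO libraries on one side of the Control libraries. It named the 10 largest changes in each direction, or the 10 with the smallest p where fewer passed. Examples from a list came from its 4 tested members with the smallest p, and a panel of 15 genes was fixed beside them. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

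The scripts were tested on simulated data made from the real means and library totals, with the same spread over counting noise for every gene. In these data 10786 genes passed the filter, and changed genes were drawn from those with a mean of at least 50 reads. At a simulated fold of 1.25 the test recovered 22.9% of the changed genes, at 1.5 it recovered 84%, at 2 it recovered 98% and at 3 it recovered 100%. These shares do not cover genes that vary more between libraries or have fewer reads. Among the simulated calls 7.36% were unchanged genes. All 5 raised lists were called, and 0 of 20 unchanged lists. Genes were drawn independently in the simulation, so its lists had no correlation between genes. It cannot show how often camera calls unchanged lists whose genes are correlated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

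The alternatives were quantile normalization, median-ratio size factors, 3 other filters, a pseudocount of 0.1, a fit that is not robust, the replicate number as a block, voom on the recovered reads and each library left out in turn. Removal of trends with GC content and exon length, and a scale without mitochondrial and small RNA genes, were added after seeing the data. Replicates were compared by a chi-square test of the recovered reads over 10766 genes, and no library repeated another.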

Results

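Gene expression was measured by RNA sequencing in vascular smooth muscle cells, the contractile cells of the artery wall, grown from mouse aorta. Cells received TMAO, a metabolite that the liver makes from trimethylamine released by gut bacteria, or control treatment for 48 h, with 3 libraries in each group. The totals implied by the FPKM values ranged from 14991252 to 16806728 reads per library. The series has a single comparison, which asks how TMAO changes the transcriptome of these cells.

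After TMAO, 8 genes rose and 12 fell. Ifit3 and Ifit1, antiviral effectors induced by interferon, rose by 50.2% and 40.6%, and Rtp4, a chaperone of receptors that is also interferon-induced, rose by 50.7%. Pla2g2e, a secreted phospholipase, rose by 63.3%. Asporin (Aspn, a small matrix proteoglycan), cholecystokinin (Cck, a peptide hormone) and osteopontin (Spp1, a matrix glycoprotein) fell by 33.1%, 28.6% and 22.2%. The transcription factor gene Cebpb fell by 45.8%.

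Of 11062 tested genes, 8 rose and 12 fell with limma at an adjusted p of 0.05, and 1448 (13.1%) had an unadjusted p below that value. Of the 20 genes past the threshold, only Mir763 changed by at least 2-fold on the scale of the test. The 3 TMAO libraries lay above all Control libraries for 1375 genes and below them for 689, together 18.7% of genes where chance gives 10%. The count of 20 became 11 (8 higher, 3 lower) without Control replicate 3, 12 (8 and 4) without TMAO replicate 1 and 56 (42 and 14) without TMAO replicate 2, and 68 when genes needed a mean of 50 reads, 32 with a filter of 1 CPM, 97 with voom on recovered reads and 0 with no filter. Quantile normalization gave 7 higher and 18 lower genes, whereas higher genes outnumbered lower ones in 5 of 6 fits that left out 1 library, among them 14 and 8 without Control replicate 1 and 12 and 8 without Control replicate 2, and with the replicate block (12 and 10).

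Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731, plus strand of mm10) went from 13.9 ± 1.27 FPKM (SD, n = 3) in Control to 20.8 ± 0.701 FPKM in TMAO. Its log2 fold change was 0.56 ± 0.067 (SE), with a limma adjusted p = 0.00876. Its neighbour Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) went from 10.9 ± 0.657 to 15.4 ± 0.199 FPKM (log2 fold change 0.46 ± 0.058, limma adjusted p = 0.0121), a call lost without Control replicate 3 or TMAO replicate 3. Ifit3b, a near-identical copy of Ifit3 with which it can share reads, had a log2 fold change of 0.61 (limma adjusted p = 0.0314) and is uncertain for that reason; the call was also lost in 6 of 17 alternatives. Rtp4 (ENSMUSG00000033355, chromosome 16, 23520291 to 23614222) went from 6.34 ± 0.390 to 9.56 ± 0.238 FPKM (log2 fold change 0.53 ± 0.064, limma adjusted p = 0.00876). Pla2g2e (ENSMUSG00000028751, chromosome 4, 138877942 to 138882817) went from 5.11 ± 0.128 to 8.35 ± 0.330 FPKM (log2 fold change 0.61 ± 0.062, limma adjusted p = 0.00335).

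Mir763, annotated as a microRNA gene within an intron of Hmga2 (ENSMUSG00000076448, chromosome 10, 120447991 to 120448110, minus strand), had a log2 fold change of 1.60 ± 0.109 and a limma adjusted p = 2.58e-04. This value rests on 2, 3 and 2 reads in the Control libraries and 11, 12 and 10 in the TMAO libraries, and the call was lost with voom on recovered reads. Hmga2 itself, chosen after its values were seen, stood at 75.0 and 78.9 FPKM (limma adjusted p = 0.596). Hmga2 lies on the same strand as Mir763, so reads of unspliced Hmga2 RNA could count for Mir763. Whether they did was not tested. Zfp382, a zinc finger gene, had a log2 fold change of 0.55 (limma adjusted p = 0.0441) that was lost in 11 of 17 alternatives. The predicted gene Gm14167, outside the naming rule and chosen after its values were seen, made up the rest of the rises. H2bc8, Tspo and Ftl1, next by p among the higher genes, did not pass, with limma adjusted p-values of 0.0523, 0.0624 and 0.0669. Reads of H2bc8 and Ftl1 can be shared with near-identical copies.

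Aspn (ENSMUSG00000021388, chromosome 13, 49544443 to 49567565) went from 97.4 ± 4.95 to 65.2 ± 0.498 FPKM, with a log2 fold change of -0.57 ± 0.046 and a limma adjusted p = 7.67e-04. Cck (ENSMUSG00000032532, chromosome 9, 121489824 to 121495694) went from 158 ± 4.03 to 113 ± 4.84 FPKM (log2 fold change -0.48 ± 0.046, limma adjusted p = 0.00228). Hmgn5 (ENSMUSG00000031245, chromosome X, 109004534 to 109013404), which codes for a nucleosome-binding protein, went from 32.0 ± 0.521 to 22.6 ± 1.11 FPKM (log2 fold change -0.48 ± 0.051, limma adjusted p = 0.00345). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), among the most abundant transcripts here, went from 1784 ± 67.3 to 1388 ± 22.7 FPKM (log2 fold change -0.36 ± 0.043, limma adjusted p = 0.00876), a call lost without Control replicate 3. Cebpb (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418) went from 5.52 ± 0.722 to 2.99 ± 0.302 FPKM (log2 fold change -0.70 ± 0.095, limma adjusted p = 0.0186) and was not called without Control replicate 3 or TMAO replicate 1.

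Gas1, which codes for a membrane protein of the Hedgehog pathway, fell with a log2 fold change of -0.44 at a limma adjusted p = 0.0187. The call was lost in 5 of 17 alternatives: with no filter, with GC and length trends removed, and without Control replicate 2, Control replicate 3 or TMAO replicate 1. The amino acid transporter gene Slc7a13 (-0.49), the integrin gene Itgb5 (-0.35) and the kinetochore gene Spc25 (-0.32) had limma adjusted p-values of 0.0441, 0.0488 and 0.0249. These 3 calls were lost in 10, 10 and 7 of 17 alternatives. The chemokine gene Ccl7 and the predicted gene Gm12415, likewise outside the rule, also fell.

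**Figure D1:**
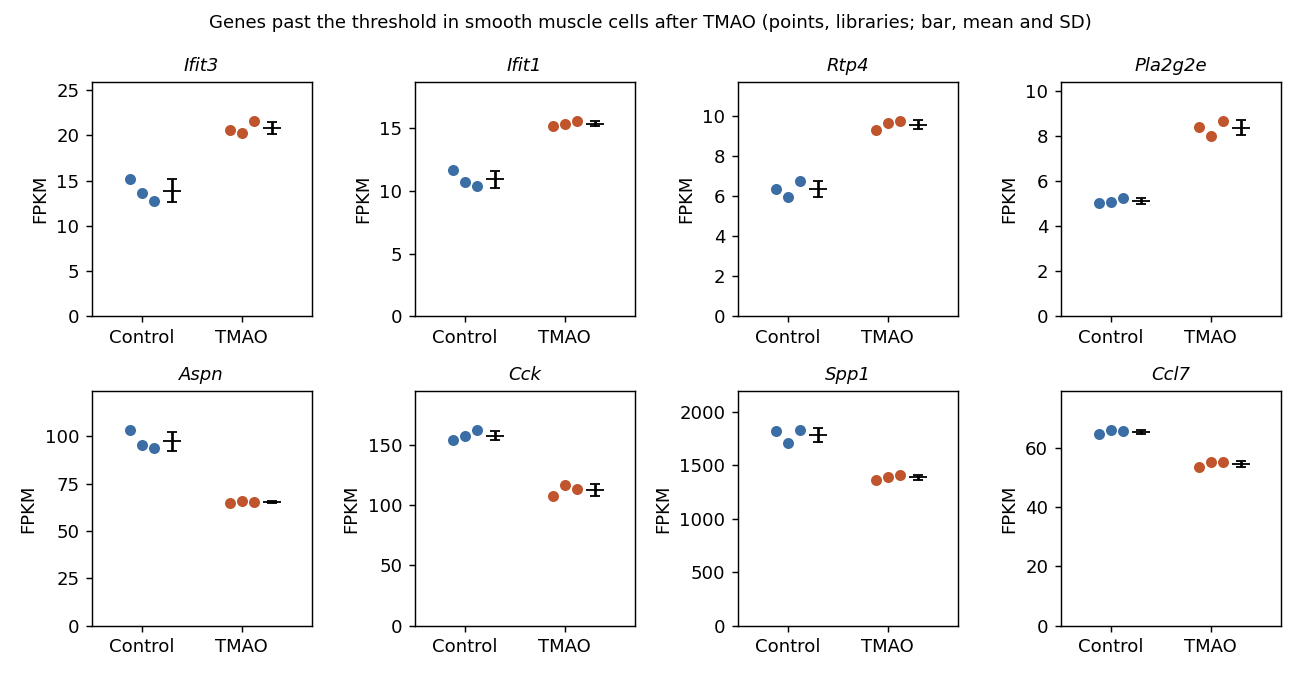
FPKM of 8 genes past the limma threshold in smooth muscle cells, with 1 point per library for the Control and TMAO groups and bars for the mean and SD (n = 3). The TMAO libraries lie above the Control libraries for Ifit3, Ifit1, Rtp4 and Pla2g2e and below them for Aspn, Cck, Spp1 and Ccl7; Spp1 went from 1784 to 1388 FPKM.

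The interferon response list was higher after TMAO, with 2 of its 13 tested genes past the threshold over all genes and 9 when adjusted over the list alone, all of them higher. Beside Ifit3 and Ifit1, the ubiquitin-like modifier Isg15 had a log2 fold change of 0.33 (limma adjusted p = 0.0798) and the tethering factor Bst2 one of 0.23 (0.0980). Camera gave the list an adjusted p = 7.96e-07, and it was not called at an adjusted p = 0.131 with an estimated correlation of -0.06. Fry, which asks whether the members move one way on balance, gave an adjusted p = 9.59e-04.

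The immediate early list, genes transcribed within minutes of a stimulus, was also higher. None of its 11 tested genes passed over all genes, 7 passed when adjusted over the list alone, and 11 of 11 had a positive log2 fold change. Fos went from 6.71 ± 0.851 to 11.3 ± 1.89 FPKM (log2 fold change 0.67, limma adjusted p = 0.0940), Junb had 0.44 (0.0940), Dusp6, which codes for a phosphatase of ERK, 0.29 (0.0891) and Btg2 0.39 (0.124). Camera gave an adjusted p = 1.45e-06, and the call was lost with adjusted p = 0.664 with an estimated correlation. Fry gave an adjusted p = 0.174. In the same TMAO libraries, reads in weak genes lying within expressed genes on the same strand had a mean of 121 RPM (reads scaled to the library total) against 65.0 RPM in Control.

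Transcripts of the mitochondrial genome were lower after TMAO, with 0 of 12 past the threshold over all genes and 7 when adjusted over the list alone. The complex I subunit genes mt-Nd4, mt-Nd2 and mt-Nd1 had log2 fold changes of -0.27, -0.22 and -0.18 and the cytochrome b gene mt-Cytb one of -0.20, with limma adjusted p-values of 0.0624, 0.0743, 0.156 and 0.131. Camera gave an adjusted p = 6.20e-07, which became adjusted p = 0.377 with an estimated correlation, and fry an adjusted p = 0.132. Under quantile normalization the list was not called (adjusted p = 0.201), and mt-Nd1 and mt-Cytb had positive log2 fold changes of 0.20 and 0.06. That scaling gives every library the same highest values, so it can hide a fall of the most abundant transcripts. Of 18 alternatives for the list, 2 lost the call, quantile normalization and the estimated correlation. Mitochondrial genes took 8.0%, 7.5% and 7.4% of the recovered reads in Control 1 to 3 and 6.5%, 6.8% and 6.8% in TMAO 1 to 3. In the same libraries the ratio of TMAO to Control was 1.855 for reads in weak genes lying within expressed genes on the same strand and 2.03 for the nuclear RNA Malat1 (chosen after its values were seen; limma adjusted p = 0.196). The nuclear genes of oxidative phosphorylation had a mean log2 fold change of -0.03 over 22 genes and a camera adjusted p = 0.898.

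The fibrillar collagen list was lower by a mean log2 fold change of -0.13, with 16 of 18 genes below 0. None passed over all genes and 1 when adjusted over the list alone, the collagen cross-linking enzyme gene Loxl1 (log2 fold change -0.22, limma adjusted p = 0.102). Col1a1 went from 185 ± 18.2 to 163 ± 7.80 FPKM (-0.18, limma adjusted p = 0.306), and Col3a1 and Col12a1 had log2 fold changes of -0.20 and -0.30. Control 2 stood apart for Col1a1, at 206.0 FPKM against 174.9 and 174.2 FPKM in Control 1 and 3, and without it the log2 fold change was -0.10 (limma adjusted p = 0.513) and the camera adjusted p of the list 0.00124. Camera gave an adjusted p = 8.63e-06, lost at adjusted p = 0.864 with an estimated correlation, and fry an adjusted p = 0.471. The list of matrix proteases and inhibitors was lower by -0.06 with 0 of 12 genes past the threshold by either adjustment. Mmp3, a stromelysin, had -0.10 and Adamts5, an aggrecanase, -0.17, while the plasminogen activator gene Plau had 0.23, none of them past the threshold. Its camera adjusted p = 0.0189 became adjusted p = 0.664 with an estimated correlation, and the call was also lost with quantile normalization, with a filter of 1 CPM, and without Control replicate 2, TMAO replicate 2 or TMAO replicate 3. Fry gave that list an adjusted p = 0.366.

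Cell cycle genes were lower by a mean log2 fold change of -0.06, with 22 of 28 below 0 and 0 past the threshold by either adjustment. Cyclin E2 (Ccne2), the spindle checkpoint kinase gene Bub1 and cyclin B1 (Ccnb1) had log2 fold changes of -0.28, -0.17 and -0.12, and the proliferation marker Mki67 went from 15.8 ± 1.18 to 13.8 ± 1.28 FPKM (-0.19, limma adjusted p = 0.333). Camera gave an adjusted p = 4.90e-04, lost at adjusted p = 0.166 with an estimated correlation of -0.02, and fry an adjusted p = 0.0365.

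**Figure D2:**
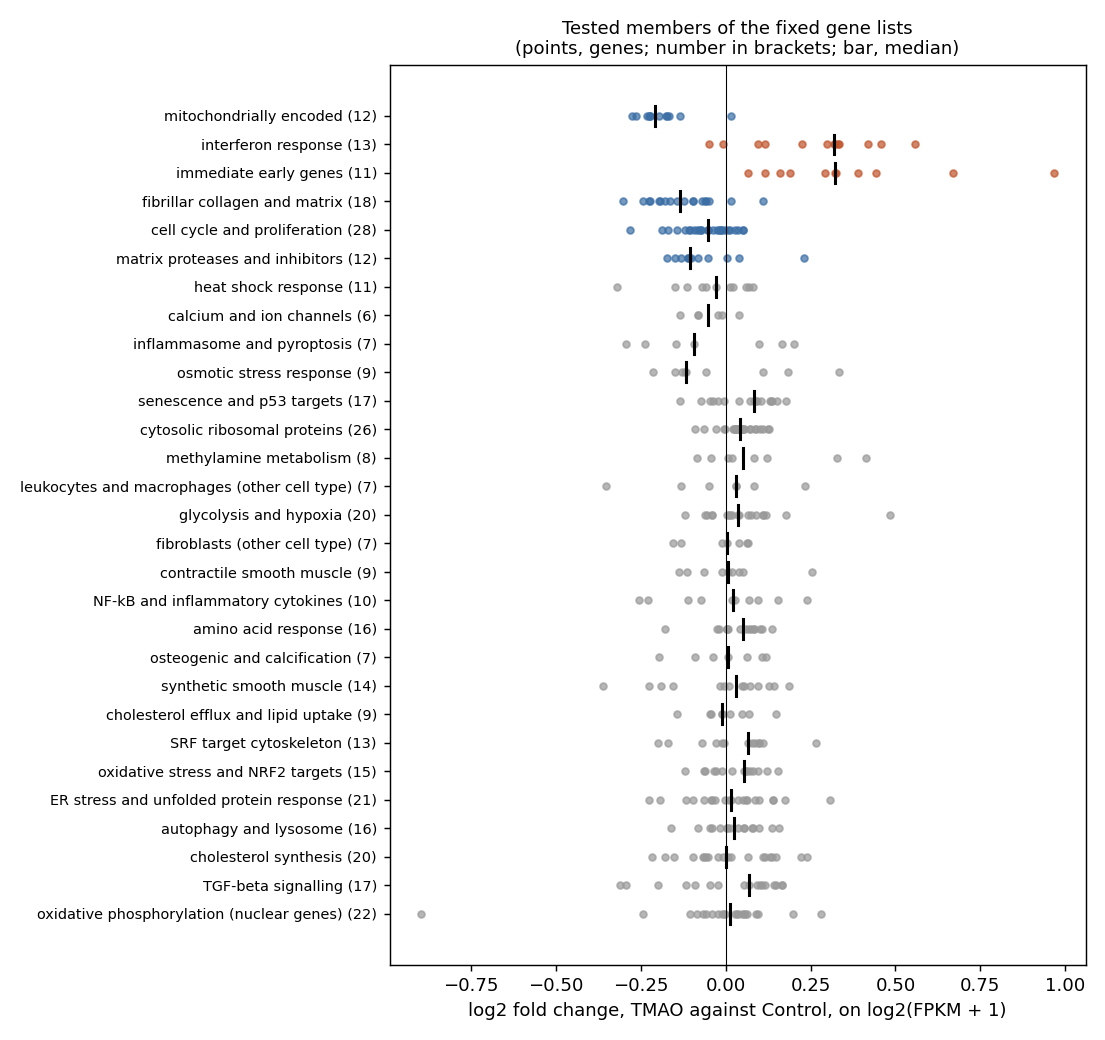
Log2 fold change of TMAO against Control, on the scale of log2(FPKM + 1), for the tested members of the 29 gene lists. Points are genes, bars are medians, and red and blue mark lists called higher and lower by camera at the preset correlation. The interferon and immediate early lists lie to the right, and 4 lists lie to the left of 0. All 6 calls were lost with an estimated correlation, which was -0.06 for the interferon and -0.02 for the cell cycle list. The mitochondrial list was not called under quantile normalization, which gives every library the same highest values.

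The contractile smooth muscle list had 0 of 9 tested genes past the threshold by either adjustment, and a camera adjusted p = 0.675. Smooth muscle actin (Acta2) stood at 487 ± 2.79 FPKM in Control and 483 ± 8.68 FPKM in TMAO (log2 fold change -0.01, limma adjusted p = 0.928). Myl9, which codes for a myosin light chain, stood at 99.1 ± 0.432 and 94.7 ± 2.04 FPKM (log2 fold change -0.07, limma adjusted p = 0.535). The contractile genes Tagln, Cnn1 and Myh11 were below the filter and not tested. Tagln stood at 0.851 ± 0.0960 and 0.766 ± 0.141 FPKM, Cnn1 at 0.702 ± 0.251 and 0.618 ± 0.0900 FPKM and Myh11 at 0.0978 ± 0.0111 and 0.0915 ± 0.00653 FPKM. Exons of Pcsk7 and a further gene on the opposite strand cover 67.9% of the exon bases of Tagln, so its level is uncertain. Pcsk7 ends at 45929726, just past the start of Tagln at 45929619. Most of the overlap therefore comes from the further gene, Gm48529, named here for its position. Actg2 had a log2 fold change of -0.14 and Des one of 0.26 (both limma adjusted p = 0.344). Of the 14 genes of the synthetic list Spp1 fell, and when adjusted over the list alone the galectin gene Lgals3 passed as well, in the other direction (0.19, limma adjusted p = 0.124 over all genes); the list had a camera adjusted p = 0.721. The reprogramming factor Klf4 had a log2 fold change of 0.05 (limma adjusted p = 0.703). The list of cytoskeletal targets of serum response factor had a camera adjusted p = 0.886.

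Inflammatory genes differed in both directions, with 1 past the threshold over all genes. In the NF-kB and cytokine list Ccl7 fell from 65.2 ± 0.720 to 54.5 ± 0.958 FPKM (log2 fold change -0.26, limma adjusted p = 0.0453), a call lost in 11 of 17 alternatives. Adjusted over the list alone, 2 genes passed as lower and 1 as higher. The chemokine genes Ccl2 and Cxcl12 had log2 fold changes of -0.23 and 0.24 (limma adjusted p = 0.180 and 0.0759), and the list had a camera adjusted p = 0.675. Il6 did not reach the filter, at 0.672 ± 0.136 FPKM in Control and 1.08 ± 0.102 FPKM in TMAO, and was not tested. In the inflammasome list 0 of 7 genes passed over all genes, and 1 higher and 2 lower genes when adjusted over the list alone. The caspase genes Casp4 and Casp1 had log2 fold changes of -0.30 and -0.24 and Txnip one of 0.20, with a camera adjusted p = 0.322 for the list. Nlrp3, the inflammasome sensor gene, stood at 0.0164 and 0.0209 FPKM, about the level of a single read per library.

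The stress lists had no gene past the threshold over all genes. The endoplasmic reticulum stress list had a camera adjusted p = 0.886 over 21 genes, with log2 fold changes of -0.03 for the sensor kinase gene Eif2ak3 (limma adjusted p = 0.916), 0.18 for Ddit3 (0.282), 0.31 for Ppp1r15a (0.217) and -0.23 for Sdf2l1 (0.180). The senescence and p53 list had a camera adjusted p = 0.391 over 17 genes, with 0.09 for Cdkn1a (limma adjusted p = 0.466) and 0.13 for Cdkn2a (0.282). Neither list had a gene past the threshold when adjusted over the list alone. The osmotic stress list, included because TMAO is an osmolyte, had a camera adjusted p = 0.391. Adjusted over the list alone, 2 genes passed as higher, Sgk1 with 0.18 and Nfat5 with 0.34. In the other direction 1 gene passed as lower, Slc5a3 with -0.215 (limma adjusted p = 0.256 over all genes). Of the 9 tested members 6 were below 0, and the median log2 fold change was -0.117. The heat shock, oxidative stress and amino acid response lists had camera adjusted p-values of 0.320, 0.886 and 0.711 and 0 genes past the threshold by either adjustment.

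Metabolic lists were not called either. In the methylamine list 0 of 8 tested genes passed over all genes. The choline pathway genes Pemt and Chka, the 2 genes of that list that passed when adjusted over the list alone, had log2 fold changes of 0.33 and 0.41 (limma adjusted p = 0.207 and 0.222). Camera gave the list an adjusted p = 0.523. Cholesterol synthesis had a camera adjusted p = 0.886, with 0 of 20 genes past the threshold over all genes and 2 higher genes adjusted over the list alone. Glycolysis and hypoxia had a camera adjusted p = 0.523, with 1 higher gene adjusted over the list alone, the growth factor gene Vegfa, at 6.75 ± 0.474 and 9.90 ± 1.55 FPKM (0.48, limma adjusted p = 0.104). The TGF-beta list had 1 higher and 1 lower gene adjusted over the list alone, Id1 (0.17) and Smad6 (-0.31), and a camera adjusted p = 0.886. In the osteogenic list 1 gene, the pyrophosphate transporter gene Ank (-0.20, limma adjusted p = 0.152), passed as lower when adjusted over the list alone, the master regulator Runx2 had a log2 fold change of -0.04 (limma adjusted p = 0.909), and camera gave an adjusted p = 0.721. Camera adjusted p-values were 0.847 for cholesterol efflux and lipid uptake, 0.886 for autophagy and lysosome, 0.322 for calcium and ion channels and 0.398 for cytosolic ribosomal proteins, with 0 genes past the threshold by either adjustment in each. Among the 29 lists, 11 had a median, mean and test that differed in sign, and none of these was called.

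Many markers of other cell types did not reach the filter, while some stood well above it. In Control the fibroblast list marker Serpinf1 stood at 254 FPKM, the adipocyte list marker Fabp4 at 13.1 FPKM and Tubb3 of the Schwann cell and neuron list at 11.1 FPKM. These levels do not show how pure the cultures were. Of the endothelial list only Emcn reached the filter, at 15.8 ± 0.685 FPKM in Control and 12.3 ± 0.192 FPKM in TMAO (log2 fold change -0.33, limma adjusted p = 0.0504, past the threshold in 6 of 17 alternatives), while Pecam1, untested and outside the rule, stood at 0.0519 and 0.0717 FPKM. The leukocyte and macrophage list had a camera adjusted p = 0.523 over 7 genes and was called without Control replicate 2. Its members Lyz2, C1qb and Tyrobp stood at 77.0 ± 7.44 and 70.0 ± 4.33 FPKM, 4.17 ± 1.23 and 4.98 ± 0.678 FPKM, and 3.94 ± 0.534 and 2.89 ± 0.586 FPKM. The fibroblast list, which cultured smooth muscle cells also express, had a camera adjusted p = 0.580 over 7 genes, with Pdgfra at 26.5 ± 1.26 and 23.8 ± 1.33 FPKM. Too few genes reached the filter for a test of the adipocyte (2 genes), Schwann cell and neuron (2), epithelial and mesothelial (2) and striated muscle (0) lists.

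Sex-linked genes were read per library as a check of the samples. Xist, the noncoding RNA of the inactive X chromosome, stood at 12.8, 15.2 and 12.5 FPKM in Control 1 to 3 and at 30.8, 22.3 and 24.0 FPKM in TMAO 1 to 3 (log2 fold change 0.87, limma adjusted p = 0.0798, past the threshold in 7 of 17 alternatives). The Y-linked genes Ddx3y, Eif2s3y and Uty were present in all 6 libraries, with log2 fold changes of -0.07, -0.05 and -0.01, and Kdm5d stood at 0.438 and 0.535 FPKM.

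The first principal component of the 500 most variable genes took 31.0% of the variance and separated the groups, from -6.47 to -3.83 in Control and from 1.26 to 8.70 in TMAO. Pairs of libraries had chi-square values per degree of freedom of 3.20 to 7.97 within a group and 6.09 to 11.57 between groups, so the ranges overlapped, and TMAO 1 and TMAO 2 were the farthest apart within a group.

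**Figure D3:**
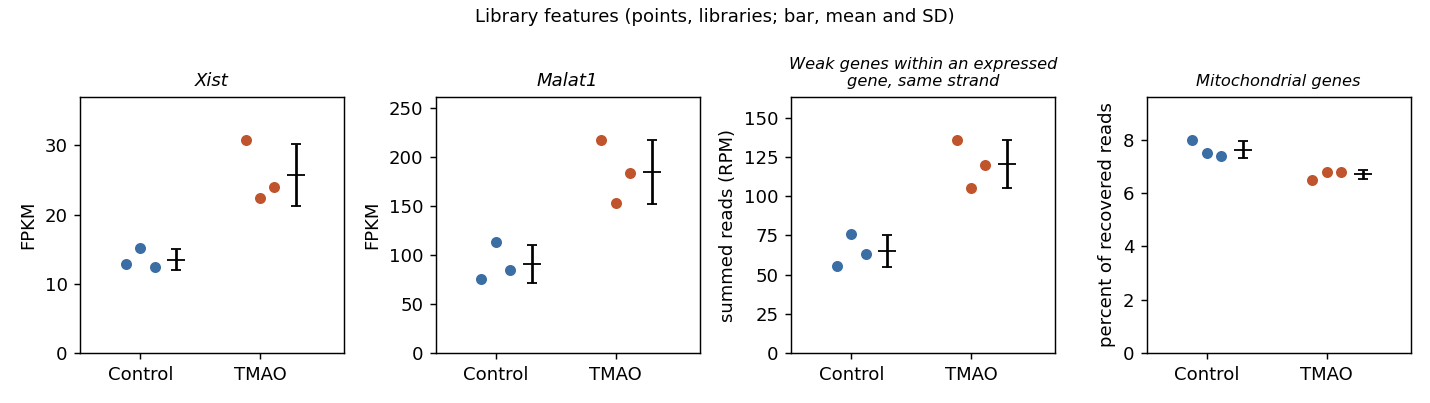
Xist and Malat1 (chosen after its values were seen) in FPKM, summed reads (RPM) in weak genes lying within an expressed gene on the same strand, and percent of recovered reads in mitochondrial genes, with 1 point per library and bars for the mean and SD (n = 3). Xist, Malat1 and the weak genes are higher in all 3 TMAO libraries, and the mitochondrial percent is lower, at 6.5% to 6.8% against 7.4% to 8.0%. Under quantile normalization, which gives every library the same highest values, mt-Nd1 and mt-Cytb had positive log2 fold changes.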

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

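The tests in this part were chosen after the number of genes above 0 had been seen, and each was fixed before its own result was known.

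Genes too weak for the gene-by-gene test that lie within an expressed gene differed between the groups when their reads were summed. Among genes with a mean under 1 FPKM, 647 lie without exon overlap within the span of a gene of at least 5 FPKM on the same strand. Their summed reads, scaled to the library total, were 55.5, 76.0 and 63.4 RPM in Control 1 to 3 and 136, 105 and 120 RPM in TMAO 1 to 3, a ratio of 1.855. The mean was higher in TMAO for 483 of the 647 genes, and without the 10 most read genes the ratio was 1.85.

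Every TMAO library also listed more genes above 0 (20844, 20368 and 20349) than every Control library (19299, 19727 and 19966). A difference in sequencing depth is argued against, since after thinning each library to the smallest number of reads the lowest TMAO library still held 495 more genes than the highest Control library. More unspliced RNA in the TMAO libraries is a candidate explanation. The ratio of TMAO to Control reads in weak genes on the strand of a host gene, divided by that in weak genes outside any other gene, was 1.74. The latter are themselves annotated genes, 5899 in number, with summed reads of 2726 RPM in Control. Their own transcripts can set their ratio, so the value of 1.74 cannot single out unspliced RNA. Genomic DNA, or reads spread over both strands, stays open. Weak genes outside any other gene had a ratio of TMAO to Control of 1.07 with overlapping libraries, which for the same reason cannot limit it. Weak genes on the opposite strand of a host gene had a ratio of 1.49. Whether TMAO itself altered the processing of RNA, or the samples differed in RNA extraction, was not tested.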

How the results depend on the processing

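Removal of GC and length trends and rescaling without mitochondrial and small RNA genes were the tests chosen after the results were seen. The fits foreseen for counts (a DESeq2 test and edgeR settings) were not run, because the values are FPKM, and scaling by the library total alone was not run, because FPKM already has it. The called genes Aspn, Cck, Hmgn5, Ifit3, Rtp4 and Pla2g2e lost their call in 1 of 17 alternatives, the fit with no filter, which called 0 genes in each direction and 0 with a 2-fold change at 1999 unadjusted p-values under 0.05. The filter of a mean of 50 reads gave 32 higher and 36 lower genes and 0 with a 2-fold change, since Mir763 has too few reads for it, and kept 17 of the 20 calls. The filter of 1 CPM gave 14 higher genes and an adjusted p of 0.0577 for the matrix protease list. Voom on recovered reads gave 43 higher and 54 lower genes, 3 of them with a 2-fold change, and kept 16 of the 20. Among genes not called, Xist passed in 7, Emcn in 6, mt-Nd4 in 4 and Fos and Vegfa in 3 of 17 alternatives. The fit that is not robust gave 2 genes with a 2-fold change. Quantile normalization also gave 2, called 2 lists lower in place of 4, gave adjusted p-values of 0.201 for the mitochondrial and 0.200 for the protease list, and turned mt-Nd1 to 0.205 and mt-Cytb to 0.063; this scaling gives every library the same highest values, and no scaling moved the median of all genes by over 0.1. With an estimated correlation camera called 0 lists higher and 0 lower. The camera adjusted p was 0.131 for interferon response, 0.166 for cell cycle, 0.377 for mitochondrial, 0.664 for immediate early and protease and 0.864 for collagen genes. The estimated correlations were -0.06 for interferon response, -0.02 for cell cycle, 0.26 for mitochondrial, 0.66 for immediate early, 0.08 for protease and 0.79 for collagen genes. A correlation above 0 therefore does not account for the lost interferon and cell cycle calls. Leaving out 1 library gave 5 to 42 higher genes, 3 to 14 lower genes, 1 to 6 with a 2-fold change, and adjusted p-values of 0.00802 to 0.0870 for the protease list. The 42 came without TMAO replicate 2, the 14 higher without Control replicate 1, the 5 without TMAO replicate 3, the 6 without Control replicate 2, the 3 lower without Control replicate 3, and 4 lower without TMAO replicate 1. For the collagen list the highest camera adjusted p with 1 library left out was 0.00318, and it was 9.23e-07 after removal of GC and length trends. Some lists were called only with 1 library left out. These were the leukocyte and macrophage list without Control replicate 2, and the ion channel and ribosomal protein lists without TMAO replicate 1. Near 0, leaving out 1 library gave -0.084 to 0.087 for Uty (above 0 without Control replicate 1 and, at 0.036, TMAO replicate 2), -0.128 to 0.018 for Ddx3y (Control replicate 1), -0.087 to 0.058 for Eif2ak3 (TMAO replicate 2) and -0.133 to 0.023 for Runx2 (TMAO replicate 3). Acta2 turned to 0.000, Uty to 0.018 and Eif2s3y to 0.005 without GC and length trends. Except where a filter or fewer samples set the change, the cause was not tested. Depth limits Mir763, with 2 to 12 reads a library, and at the smallest simulated fold the test recovered 22.9% of changed genes.

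The values showed no clear pairing of the samples by replicate number. Deviations of same-numbered libraries from their group means correlated at -0.086, -0.104 and 0.056 across genes. Control 3, but not Control 1 or 2, correlated best with its own number. With 3 libraries in a group, these correlations cannot show whether the numbers mark shared animals or days. With the replicate number as a block, 12 genes were higher and 10 lower, 4 of them by 2-fold, 14 of the 20 calls were shared, and all 6 list calls held.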

Other observations

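In this part, the test on Y-linked genes was chosen only after its values were seen, as were the genes Malat1, Neat1, Firre, Egr1, Tpm2, Cald1 and Tpm1. The tests on nuclear RNAs, on exon overlap and on other splits were fixed before their results were known.

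Some long noncoding RNAs that stay in the nucleus had higher means after TMAO and did not pass the test. Malat1, a component of nuclear speckles, stood at 90.8 ± 19.7 FPKM in Control and 185 ± 32.3 FPKM in TMAO (n = 3, log2 fold change 1.02, limma adjusted p = 0.196). Neat1, the scaffold of paraspeckles, had a log2 fold change of 0.53 (limma adjusted p = 0.231) and Firre one of 0.47 (0.139). The immediate early transcription factor gene Egr1 stood at 9.02 ± 0.977 and 18.8 ± 4.09 FPKM (log2 fold change 0.97, limma adjusted p = 0.127) and passed without TMAO replicate 2. All 3 TMAO libraries lay above all 3 Control libraries for Malat1, Neat1 and Egr1.

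Xist was higher in all 3 TMAO libraries while Y-linked genes stayed near their Control level. A larger share of female cells in the TMAO cultures would lower Y-linked genes, and their mean log2 difference was -0.043 with a 95% interval of -0.240 to 0.154, which leaves a moderate shift open. More nuclear RNA in the TMAO libraries may be another source, and the median log2 fold change of 6 tested nuclear RNAs was 0.250, with 4 of 6 above 0. The 95% interval of this median, -0.050 to 0.777, came from resampling the 6 RNAs and does not measure the spread between libraries. It includes 0.437, the bound set from the change of Xist, so neither explanation was excluded. An effect of TMAO on Xist itself remains untested.

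Tagln, Myh11 and Cnn1 stood under 1 FPKM in Control, while other contractile genes were well above that level, with Acta2 at 487, Tpm2 at 115, Myl9 at 99.1, Cald1 at 77.5 and Tpm1 at 76.0 FPKM. For Tagln, reads that fall where exons of a gene on the opposite strand overlap may have been dropped in counting, since 67.9% of its exon bases lie in such exons, but the other bases should still give reads, and the strand setting is not given in the sources used here. For Myh11 and Cnn1 this is argued against, because 0.0% of their exon bases overlap another gene. No biological explanation was tested, since no group of the design gives one.

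The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 20 genes, and the highest other split gave 1 gene. For gene lists, the real split gave 6 calls and the highest other split 5. The other splits ranged from 0 to 5 lists, so mixed groupings also gave list calls at the preset correlation. In each case 1 of the 10 splits, the real one, gave as many.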
